A study of Mus musculus with 10 samples.

How the data were processed

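Total RNA from mIMCD-3 cells, an established mouse line of the inner medullary collecting duct, was measured on single-colour miRNA arrays in 5 samples given 100 nM aldosterone and 5 given the ethanol vehicle. Per the labels' protocols, 70000 cells were seeded on transwell filters in medium with 10% serum, held for 24 h in hormone-free medium after reaching confluence, and lysed in TRIzol after treatment, and 500 ng of RNA was labelled with Hy5 dye. The duration of treatment and the scanner are not given in the sources used here. Nothing in the labels says whether the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

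Each deposited array file lists a raw intensity for 3136 spots, of which 778 are blank, with every miRNA probe spotted 2 times. Per the deposited note on the columns, the authors subtracted the mean of the blank spots, kept a spot where its intensity lay above that mean plus 2 SD, averaged the kept duplicates and scaled each array so that the median of its detected averages was 25. The series value table held the same numbers as the normalized column of the array files (6454 values, largest difference 0), and each of its columns had a median of 25. Its direction and scale were therefore known, and it served as an alternative. Because it leaves out spots under the threshold, a dim probe has a value in it only on arrays where a spot passed. Comparisons of dim probes in it can therefore rest on few arrays. A miRNA name is the one printed in the file, in an older nomenclature in which an asterisk marks the minor strand. A table of mouse gene names for the assembly GRCm38.p6 listed 1198 miRNA genes, and since the files name no genome build, no coordinates are given.

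The raw intensity was used for all comparisons. Its background was corrected with normexp at an offset of 50, the log2 values of the 2 spots of a probe were averaged, and arrays were then quantile-normalized (R 4.3.3, limma 3.58.1). Intensities in the text are back-transformed with the offset taken off, so they are intensity units above background. Most signals are small beside the offset, and a log2 change on the log2(intensity + 50) scale therefore understates the change of dim probes. After normalization 58 tested probes, bright and dim, were tied within at least 1 same-numbered pair (log2 values less than 1e-09 apart) and 5 within 3 or more. In simulations a 2-fold change, planted only in probes detected on all arrays, appeared as a median log2 change of 0.308 when 90 probes were changed. The 4 spots that carry the file's own quality flag were left out. A probe counted as detected on an array where both of its spots passed the authors' threshold. Probes with a mouse miRNA name that were detected on at least 5 of the 10 arrays were tested, 430 of 1040. The 39 probes for viral miRNAs were not tested against treatment. Levels of different probes are not set against each other, since hybridization efficiency differs between probes.

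Aldosterone was compared with vehicle by limma's lmFit and eBayes, two-sided, without a block, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The number of detected probes per array was compared by an exact permutation test over all splits of the arrays into 5 and 5. Lists of related miRNAs, 20 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested, which held for 15, and with an estimated correlation and fry beside it. The miRNAs named were chosen by rule: up to 10 in each direction with the largest change among those past the threshold and moving one way in all 5 pairs, filled up by smallest unadjusted p where fewer passed; every tested member of the lists of aldosterone-responsive miRNAs, mineralocorticoid pathway regulators and endothelin-1 regulators; and from each other list the 2 to 4 members with the smallest unadjusted p. Any other miRNA named was chosen after its values were seen, and its text says so or gives its level without a comparison. The tests, lists, named-miRNA rule and most alternatives were fixed before the data were examined.

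Sample titles of the 2 groups share 5 starting codes, which were numbered as replicates 1 to 5. Samples with the same number were checked for pairing before the fits were compared. Deviations from the group means correlated between same-numbered arrays at r of 0.2 to 0.81, and 9 of the 10 arrays correlated best with the array of their own number, so the numbers pair the samples although the labels do not say what the shared code stands for. A fit with the replicate number as a block was run as the alternative for every test. The SD of log2 differences between arrays of a group was 0.365 to 1.04, against 0.277 from duplicate-spot noise, so no array file repeats another, but a second hybridization of the same RNA is not excluded by this.

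The procedure was tested on simulated changes planted in regroupings of the real arrays. With 90 of the 430 probes changed in each of 10 regroupings, 34% of probes changed 1.5-fold, 75.3% of those changed 2-fold and 97.7% of those changed 4-fold were called. With 12 changed probes these shares were 7.5%, 47.5% and 100%. The changes were planted only in the 244 probes detected on all 10 arrays, so these shares do not hold for the dimmer tested probes. A list of 6 members changed 2-fold was called in 10 of 10 regroupings, and 0 of 127 unchanged lists were called. These lists were random draws from the probes detected on all arrays. Families whose members vary together, such as miR-200 (estimated correlation 0.858 without the block), were not simulated. The 0 of 127 therefore does not give the rate of false calls for the lists tested. Alternatives covered background correction, the offset, normalization between arrays, the filter on dim probes, the deposited value table, the replicate block, the style of the sample titles as a block, the model's variance prior, and leaving out single arrays or pairs. A slide or scan batch as a block was not run, since no slide or scan field was among the columns used here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.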

Results

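Aldosterone, the mineralocorticoid hormone that acts on the distal nephron and collecting duct, was given at 100 nM to mIMCD-3 cells, and miRNAs were measured in 5 aldosterone and 5 vehicle samples. The array carried 1040 probes with mouse miRNA names, of which 12 stood for several miRNAs at once. The mean of the blank spots was 17.6 to 21.5 intensity units per array with an SD of 0.939 to 1.34, and the median CV between duplicate spots was 10.4% to 13.6%. The number of arrays limits the precision of every value below.

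The first question, named in the title of the series, was which miRNAs the cell line contains. Of the 1040 mouse probes, 244 were above the authors' detection threshold on all 10 arrays, 254 on 1 to 4 arrays and 356 on none. Probes for viral miRNAs passed it on all 10 arrays at a rate not much lower, 7 of 39. Detection alone, above all of dim probes, therefore does not show that a miRNA is present. The miR-200 family, which represses the transcription factors ZEB1 and ZEB2 in epithelial cells, was detected through miR-200a, miR-200b and miR-429 on all 10 arrays. Vehicle intensity was 82.0 ± 38.8 for miR-200a, 89.9 ± 35.4 for miR-200b and 31.3 ± 19.4 for miR-429 (SD, n = 5). The other strands and members of that family were at or near background, with miR-141 detected on 1 array and miR-200c on 2. Among kidney-enriched miRNAs, 8 of 20 probes were detected on all 10 arrays, among them miR-10a (305 ± 67.8 in vehicle), miR-10b (76.8 ± 10.9), miR-194 (9.8 ± 2.3) and miR-196a (17.6 ± 7.1), while miR-192, which shares clusters with miR-194, was detected on 9 arrays at 8.36 ± 0.53 in vehicle. The 8 also include the minor strands miR-10a*, miR-204* and miR-211*, while miR-204 itself was detected on 7 arrays and miR-211 on 2.

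The let-7 family, associated with differentiated cells, had 9 of 20 probes detected on all arrays, with vehicle intensities of 661 ± 171 for let-7a, 538 ± 119 for let-7c and 477 ± 48.9 for let-7d (SD, n = 5). All 11 probes of the miR-30 family were detected on at least 1 array and 7 on all 10, including miR-30a at 338 ± 146 and miR-30c at 497 ± 105 in vehicle. The growth-associated miR-17~92 cluster and its paralogs had 14 of 28 probes detected on all arrays (miR-17 at 221 ± 55.1, miR-93 at 222.1 ± 36.9), and the miR-232427 clusters 6 of 11 (miR-23a at 376 ± 84.1, miR-24 at 193 ± 36.7). Of the miR-29 family, whose targets include collagens, 3 of 7 probes were detected throughout, with miR-29a at 420 ± 71.9. The miR-221, miR-222 and miR-31 group had 4 of 6 probes detected on all arrays (miR-31 at 193 ± 27.7 in vehicle).

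Markers of other cell types were mostly at background. Blood cell markers had 0 of 9 probes detected on all arrays and 7 on none. Only miR-206 at 10.1 ± 3.07 in vehicle was detected throughout among 15 probes for muscle miRNAs, and 12 of those were detected on no array. For neuron markers, 3 of 14 probes were detected on all arrays, all of them strands of miR-128, and 8 on none. Endothelium and fibroblast markers had 0 of 10 on all arrays (miR-126-3p on 9), and liver and islet markers 1 of 4, the minor strand miR-375*. The embryonic stem cell clusters had 0 of 24 probes on all arrays and 14 on none. In the imprinted Dlk1-Dio3 cluster 3 of 78 probes, miR-370, miR-494 and miR-667, were detected on all arrays and 40 on none.

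Aldosterone arrays had 460.6 ± 78.4 detected mouse probes and vehicle arrays 391.8 ± 84.3 (SD, n = 5 each), a difference of 68.8 that did not exceed the spread between arrays (exact permutation p = 0.2063, two-sided, over all splits into 5 and 5). It was 38.2 in detected mouse miRNA probes per array without aldosterone replicate 3 and 39.6 without vehicle replicate 2. The count was higher with aldosterone in 4 of 5 same-numbered pairs (exact sign-flip p = 0.125, where the smallest possible is 0.0625). Before normalization the median log2 signal of probes detected on all arrays was 4.57 ± 0.75 with aldosterone and 4.02 ± 0.74 with vehicle, higher in 5 of 5 pairs by 0.54 on average (exact sign-flip p = 0.0625, the smallest possible; exact permutation p = 0.2937). Spots named as spike controls were also higher with aldosterone by 0.19 on the log2 scale in 4 of 5 pairs (exact sign-flip p = 0.1875, exact permutation p = 0.06349, n = 5 each).

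**Figure D1:**
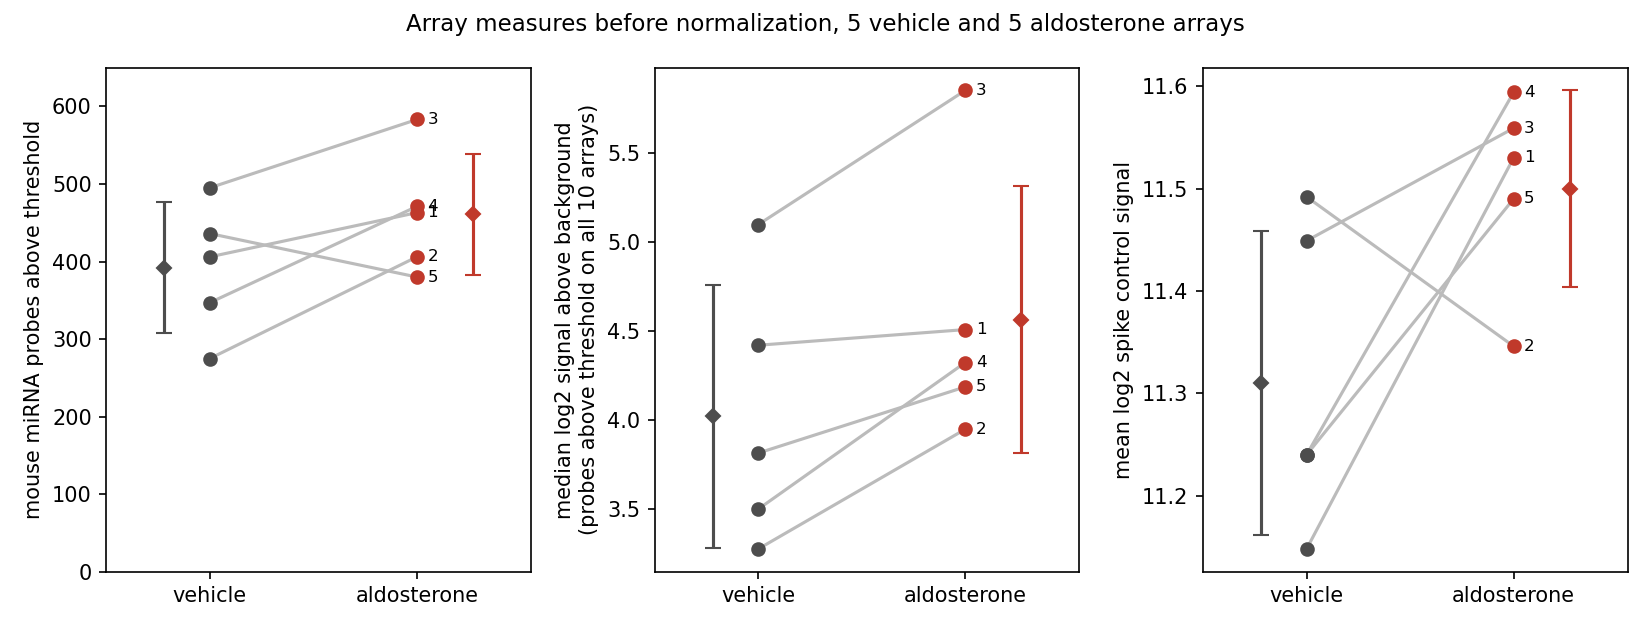
Detected mouse miRNA probes, median log2 signal above background of the probes detected on all 10 arrays, and mean log2 spike control signal, for 5 vehicle and 5 aldosterone arrays; lines join arrays with the same replicate number, printed at the right, and diamonds with bars are mean ± SD. The vehicle arrays hold 275 to 495 detected probes and the aldosterone arrays 380 to 583, and the signal panels do not start at 0.

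The second question was whether aldosterone altered the level of individual miRNAs. None of the 430 tested miRNA probes passed the threshold in either direction (limma, smallest adjusted p = 0.9445). At an unadjusted p under 0.05 were 8, 4 higher and 4 lower, where 21.5 would be expected by chance. This fit leaves differences between replicate numbers in its error, which can lower that count. With the replicate block it was 19. miR-21, an injury-associated miRNA of the renal epithelium, had a log2 change of 0.70 (SE 0.38, 95% interval -0.17 to 1.56), from 1111 ± 556 with vehicle to 1736 ± 696 with aldosterone (SD, n = 5), and was higher in 4 of 5 pairs and tied in the other. Its normalized values are steps between a few top ranks, and under cyclic loess its log2 change was 0.345. miR-29b was at 188 ± 63.8 with aldosterone and 126 ± 85.3 with vehicle (log2 change 0.52, SE 0.32), and miR-30a at 437 ± 150 and 338 ± 146 (0.35, SE 0.29). On the lower side miR-3102* was at 191 ± 48.0 with aldosterone and 275 ± 94.4 with vehicle (log2 change -0.40, SE 0.20), although it lay on the higher side without normalization between arrays (0.17), under spike control scaling and in the deposited table. Most tested probes were higher in those settings (96%, 75.6% and 85.6%). None of these 4 differences passed the threshold without the replicate block (limma adjusted p = 0.9445) or with it (adjusted p = 0.7438), although within pairs miR-30a was higher in 5 of 5 (SE 0.08 with the block) and miR-3102* lower in 5 of 5 (SE 0.08). Single arrays moved all 4 values. Without vehicle replicate 2 the log2 change was 0.435 for miR-21 and 0.311 for miR-29b (without replicate 2 in both groups 0.428 and 0.202). For miR-30a it was 0.189 without vehicle replicate 1, 0.226 without aldosterone replicate 3 and 0.537 without vehicle replicate 3. For miR-3102* it was -0.267 without vehicle replicate 4. Each single-array removal splits a pair, so differences between replicate numbers enter the fit. Leaving out whole pairs moved neither miR-30a nor miR-3102* by over 1.5 times.

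The 10 miRNAs with the smallest unadjusted p on the higher side, none past the threshold, were miR-467d*, miR-148a, miR-1306, miR-466m-5p (shared with miR-669m-5p), miR-679-3p, miR-669a-3p (shared with miR-669o-3p), miR-125a-3p, miR-1943*, miR-700* and miR-1982*. All but miR-125a-3p were dim. miR-467d* was at 7.18 ± 0.92 with aldosterone and 5.54 ± 0.89 with vehicle (SD, n = 5), detected on 5 and 1 arrays, and miR-148a at 4.96 ± 0.69 and 3.71 ± 0.62, detected on 4 and 1. miR-125a-3p was at 52.4 ± 8.76 and 41.2 ± 9.99 (log2 change 0.17, SE 0.08; 0.086 without replicate 2). Of these 10, all except miR-125a-3p lay on the lower side when arrays were scaled to their 75th percentile instead. Under that scaling only 13.5% of all tested probes were higher. On the lower side the 10 were miR-3102-3p.2, miR-877, miR-683, miR-93*, miR-106b*, miR-290-5p, miR-3102*, miR-28*, miR-3104-5p and miR-574-3p. Of these 10, miR-106b*, miR-28*, miR-3104-5p, miR-574-3p and miR-3102* lay on the higher side both without normalization between arrays and in the deposited table. In these settings 96% and 85.6% of all tested probes were higher. miR-3102-3p.2 was at 6.50 ± 0.32 with aldosterone and 8.22 ± 0.89 with vehicle, miR-877 at 4.83 ± 0.85 and 6.70 ± 0.999, and miR-106b*, the minor strand of a miR-17 paralog, at 13.0 ± 1.73 and 15.9 ± 2.56.

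Precision differed with brightness. The 95% interval of the log2 change reached 0.059 to either side in the median and 0.328 at its 90th percentile on the compressed scale, and for 428 of 430 probes it lay within a change of 1 log2 unit. A planted 2-fold change appeared as a median of only 0.308 on this scale, so these intervals do not exclude 2-fold changes. For dim probes the offset alone keeps the log2 change small. With the replicate number as a block, 0 probes passed (limma, smallest adjusted p = 0.7438) and 19 were at an unadjusted p under 0.05, 11 higher and 8 lower. The median SE was 0.022 with the block and 0.026 without it, and SEs given here are without it unless stated. In all 5 pairs 16 probes were higher and 10 lower, where 26.9 such probes would be expected by chance if none were tied. The 58 probes tied in a pair could not count, so that number is somewhat too high. Of the 75 named miRNAs, 63 had a log2 change that moved by over 1.5 times when some single array or pair was left out, 30 of them without vehicle replicate 2.

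Lists of related miRNAs gave 0 of 15 past the threshold (limma camera, smallest adjusted p = 0.1868, for the miR-466, miR-467 and miR-669 repeat cluster and for endothelium and fibroblast markers), and in each of the 20 lists 0 members passed over all tested probes or adjusted over the list alone. All 3 tested members of the epithelial miR-200 family were higher with aldosterone. miR-200a was at 106 ± 33.6 against 82.0 ± 38.8 (log2 change 0.26, SE 0.20), miR-429 at 36.8 ± 16.4 against 31.3 ± 19.4 (0.11, SE 0.17) and miR-200b at 99.9 ± 33.1 against 89.9 ± 35.4 (0.11, SE 0.19), with SD over n = 5. They were higher in 5, 4 and 3 of the 5 pairs. Without aldosterone replicate 3 the log2 changes of miR-200a, miR-429 and miR-200b were 0.142, -0.001 and 0. They were 0.42, 0.232 and 0.239 without vehicle replicate 3. Both arrays of replicate 3 were high (miR-200a at 161.2 with aldosterone and 151.1 with vehicle), so leaving out 1 shifts the fit by that height. Leaving out both moved none of the 3 by over 1.5 times. Without vehicle replicate 2, miR-429 was at 0.003 and miR-200b at 0.007 (miR-429 at 0.051 without replicate 2 in both groups). The family did not pass without the block (limma camera adjusted p = 0.2721). With the replicate block it passed (adjusted p = 0.04518), and it did not with the block and an estimated correlation (adjusted p = 0.3808).

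In the miR-30 family 6 of 8 tested members were higher and 2 lower, with a median log2 change of 0.084; miR-30d was at 276 ± 82.4 with aldosterone and 224 ± 66.4 with vehicle, and miR-30b at 94.1 ± 11.7 and 78.1 ± 20.4 (SD, n = 5). In the miR-29 family 5 of 6 were higher (miR-29c at 23.6 ± 3.82 and 19.4 ± 6.996; miR-29a at 447 ± 69.1 and 420 ± 71.9). Of the miR-232427 clusters 5 of 8 were higher, with miR-27b at 58.0 ± 6.24 and 48.4 ± 10.8. Among injury and fibrosis miRNAs 8 of 10 were higher, including miR-34a, a p53 target, at 39.4 ± 10.8 and 33.7 ± 7.21. The let-7 family had 7 of 12 higher and 5 lower (let-7i at 144 ± 20.5 and 129 ± 32.5; let-7d at 446 ± 49.1 and 477 ± 48.9), and the miR-17~92 list 11 of 19 higher and 8 lower (miR-106a at 121 ± 18.0 and 103 ± 15.7; miR-92a at 42.4 ± 5.32 and 50.0 ± 8.86). None of these lists passed without the replicate block (limma camera adjusted p = 0.2671 to 0.8625) or with it (0.09637 to 0.8921). The smallest value was that of the miR-30, miR-29 and injury lists. Within pairs miR-30d, miR-29a and miR-27b were higher in 5 of 5, and let-7d and miR-92a were lower in 4. None of these 5 miRNAs passed with the block (limma adjusted p = 0.7438). The medians of the injury, let-7 and miR-17~92 lists turned to the lower side under 75th percentile scaling, that of let-7 also under cyclic loess. Under 75th percentile scaling only 13.5% of all tested probes were higher.

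Of the 3 probes for miRNAs listed as aldosterone-responsive in cortical collecting duct cells, miR-335-3p was detected on 1 array and not tested. miR-290-5p was at 6.11 ± 0.77 with aldosterone and 8.38 ± 2.36 with vehicle, and miR-1983 at 13.8 ± 4.24 and 10.3 ± 4.21 (SD, n = 5), neither past the threshold. Without vehicle replicate 2 their log2 changes went from -0.056 to -0.037 and from 0.082 to 0.037. Of the mineralocorticoid pathway regulators, a list that includes miR-124 and miR-135a, miRNAs that target the mineralocorticoid receptor, 2 of 10 probes were tested, miR-192 at 7.63 ± 0.77 and 8.36 ± 0.53 and miR-466g at 6.99 ± 1.22 and 6.72 ± 1.101. The endothelin-1 regulators, chosen partly from recalled work on this cell line that may rest on these samples and so not independent evidence, had 1 of 5 tested members higher and 4 lower. miR-709 was at 1193 ± 282 and 1569 ± 795, lower in 2 pairs and tied in 3, miR-125a-5p at 44.4 ± 2.18 and 55.7 ± 26.3, miR-125b-5p at 50.1 ± 14.9 and 60.3 ± 18.5, miR-155 at 29.7 ± 6.64 and 28.1 ± 13.2, and miR-1187 at 11.1 ± 1.41 and 11.3 ± 1.13. Vehicle replicate 2 carries much of this: without it the log2 change of miR-709 went from -0.292 to -0.045, that of miR-125a-5p from -0.134 to 0.005, that of miR-125b-5p from -0.136 to -0.07 and that of miR-155 from 0.042 to -0.049. The normalized values of miR-709 are also steps between a few top ranks. The list did not pass (limma camera adjusted p = 0.2721). Its 5 members lay on the higher side without normalization between arrays and in the deposited table, as did 96% and 85.6% of all tested probes.

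Kidney-enriched miRNAs had 5 of 11 tested members higher and 6 lower (miR-196b at 24.6 ± 3.37 and 21.6 ± 8.14; miR-211* at 78.6 ± 11.4 and 101 ± 28.5; camera adjusted p = 0.4412), and the miR-221, miR-222 and miR-31 group 2 of 5 higher (miR-221 at 63.8 ± 7.25 and 70.6 ± 5.63; adjusted p = 0.2721), with both medians on the higher side without normalization, under spike control scaling and in the deposited table. In those settings 96%, 75.6% and 85.6% of all tested probes were higher. The log2 change of miR-196b went from 0.065 to 0.009 without vehicle replicate 2, and that of miR-211* from -0.216 to -0.125 without vehicle replicate 4. In the miR-466, miR-467 and miR-669 repeat cluster 21 of 32 tested members were higher, with a median log2 change of 0.007. It turned negative under 75th percentile scaling, where only 13.5% of all tested probes were higher. This list passed when aldosterone replicate 3 (limma camera adjusted p = 0.0002369) or vehicle replicate 2 (adjusted p = 0.01813) was left out, and with an estimated correlation it did not (adjusted p = 0.3346 and 0.7388). Neuron markers (4 tested), endothelium and fibroblast markers (3), embryonic stem cell clusters (3) and the Dlk1-Dio3 cluster (13) had median log2 changes between -0.007 and 0.019 and did not pass (limma camera adjusted p = 0.1868 to 0.7193). Blood, muscle, and liver and islet lists had 1 tested member each (miR-150, miR-206 and miR-375*) and no list test. When arrays were scaled to their 75th percentile, 4 lists passed, the miR-200, miR-30, miR-232427 and miR-17~92 lists, and 0 of them did with an estimated correlation (limma camera adjusted p = 0.2478 to 0.3583).

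**Figure D2:**
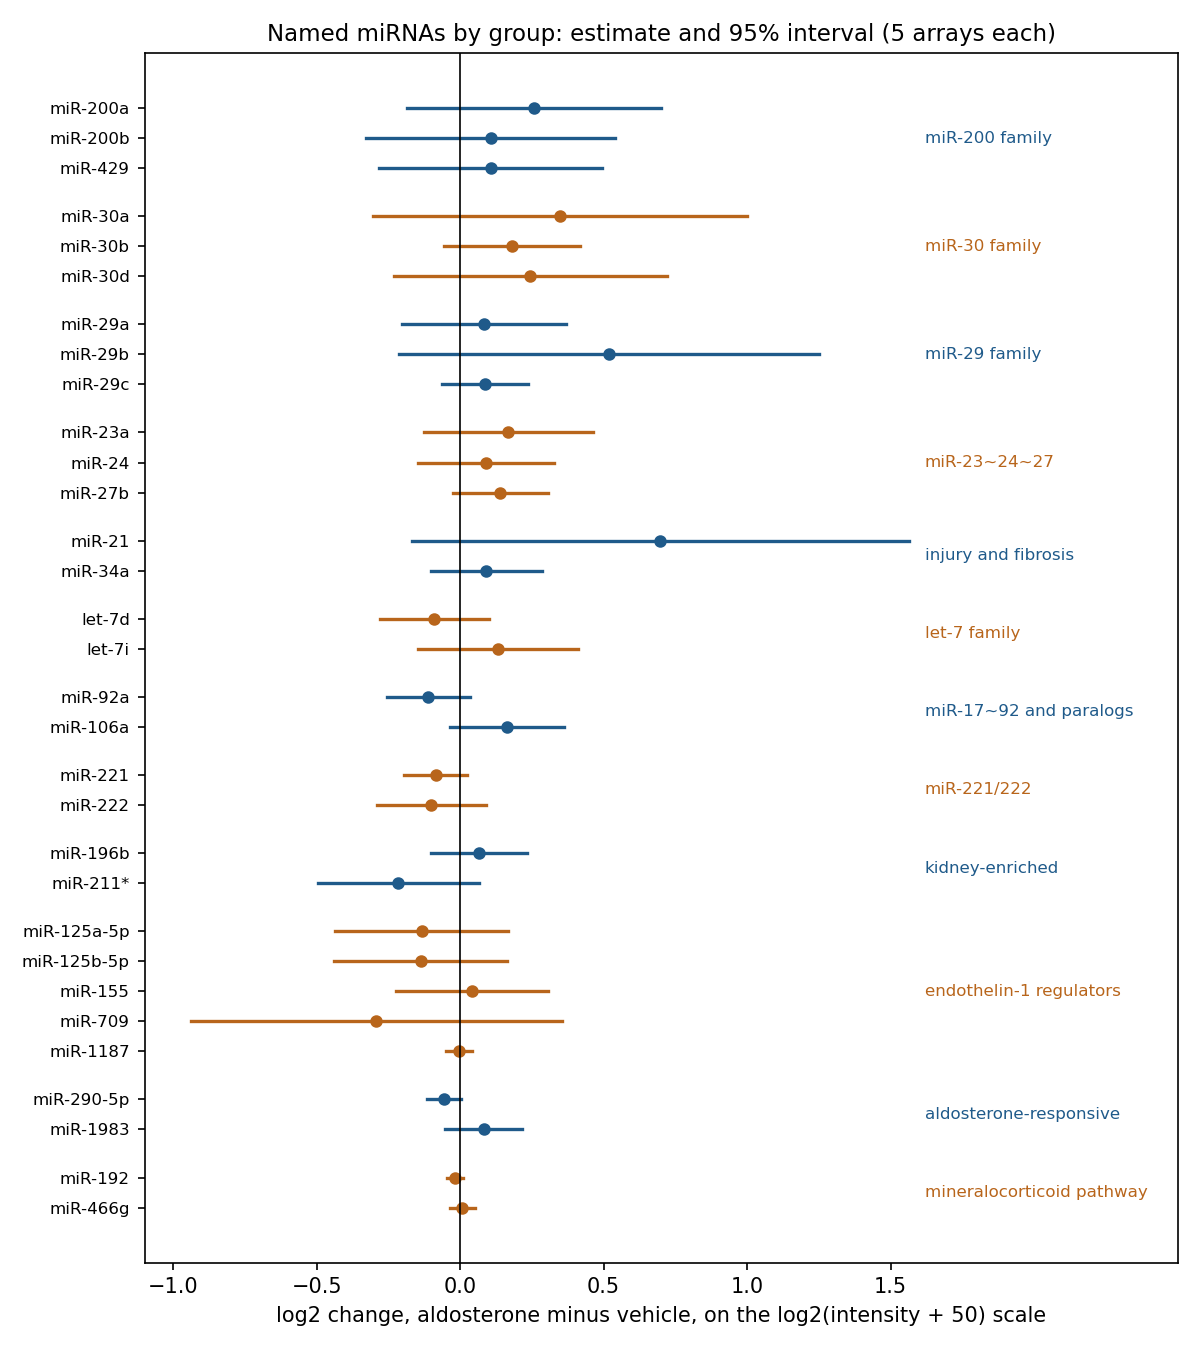
Log2 change with aldosterone against vehicle (x axis, on the log2(intensity + 50) scale) for a selection of the named miRNAs grouped by list, without the repeat cluster and without most miRNAs named by smallest p. Points are estimates, and lines are 95% intervals from the limma fit without the replicate block over 5 arrays per group. The interval of miR-21 runs from -0.17 to 1.56.

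Samples fall into 2 title styles, 3 pairs with a P-number in the title and 2 pairs without. The aldosterone effect differed between these styles for 0 of 430 probes (limma interaction, smallest adjusted p = 0.9944), with 7 at an unadjusted p under 0.05. Differences between replicate numbers, measured with treatment in the model, passed the threshold for 10 probes (limma F-test, adjusted p = 0.005569 to 0.03781), named here after their values were seen: miR-210, miR-324-5p, miR-29a, miR-146a, miR-2137, miR-10a, miR-200b, miR-30a, miR-33 and miR-22*. miR-210, a hypoxia-induced miRNA, had pair means from 12.1 in replicate 1 to 71.5 in replicate 3, a ratio of 5.93. miR-146a, an NF-kappaB target, ranged from 3.9 to 15.3 and miR-30a from 225 to 588.

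**Figure D3:**
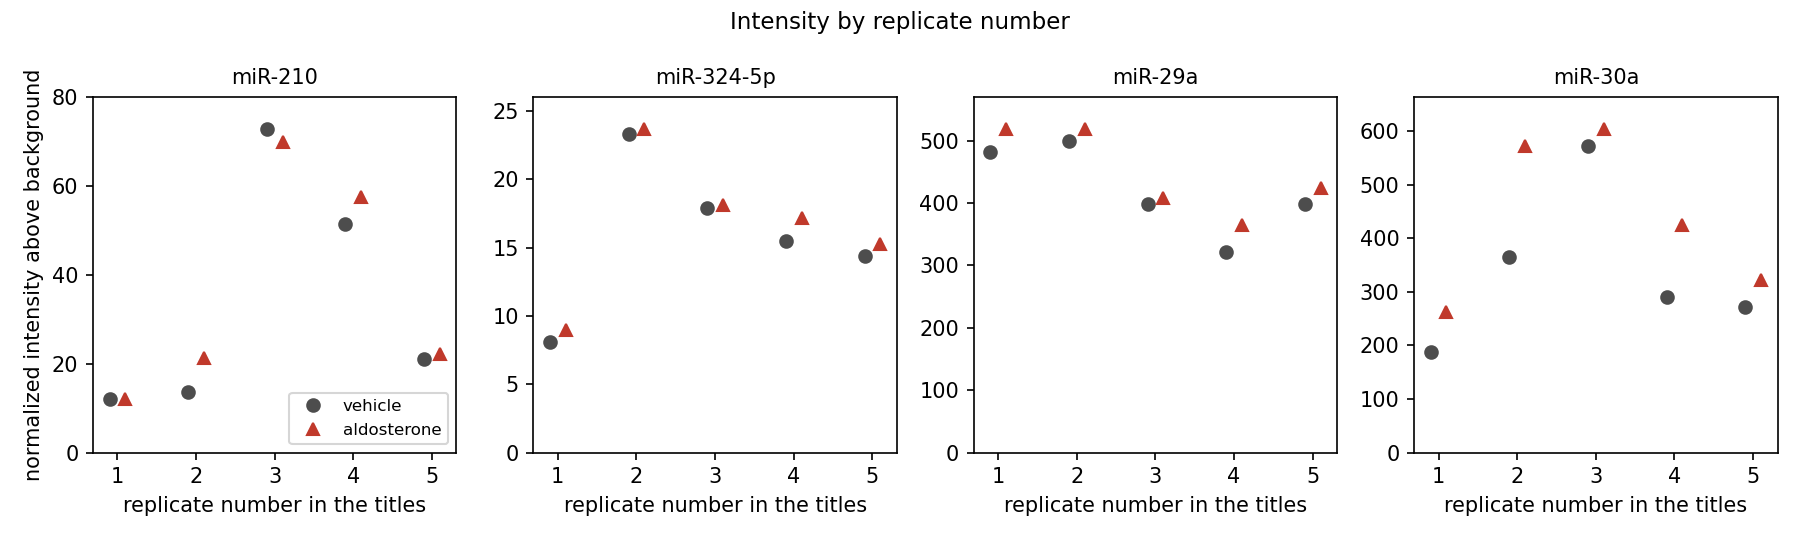
Normalized intensity above background (y axis, from 0) of miR-210, miR-324-5p, miR-29a and miR-30a by replicate number (x axis), with circles for vehicle and triangles for aldosterone, 1 array per symbol. Both miR-210 values of replicate 3 (72.9 with vehicle and 70.0 with aldosterone) lie far above both of replicate 1 (12 and 12.1).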

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

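The tests of array brightness before normalization, and the comparison of the count past the adjusted threshold with other splits, were chosen after those results had been seen; the other tests here were not. In 13 of the 156 groups of 5 arrays examined, 1 array stood far from the other 4, where chance gives about 7.8. In vehicle replicate 2, miR-106b* was at 20.4 (others 14.2 to 15.6) and miR-125a-5p at 102 (39 to 50.7). In vehicle replicate 3, miR-200a was at 151 (60.2 to 68.3), miR-29c at 31.5 (13.3 to 18.1) and miR-292-3p at 4.06 (5.54 to 5.93). Aldosterone replicate 3 had miR-21 at 2910 (1210 to 1680), miR-429 at 65.6 (25.2 to 33.4), miR-196b at 30.4 (21.9 to 24.2) and miR-204 at 9.38 (5.53 to 6.44). In aldosterone replicate 5, miR-709 was at 1680 (1030 to 1210) and miR-24 at 245 (195 to 199). The remaining ones were let-7d* at 7.72 in aldosterone replicate 1 (5.04 to 5.41) and miR-206 at 15.3 in vehicle replicate 1 (7.35 to 9.49). Several of these values are not peculiar to 1 array, since the same-numbered array of the other group was also high. Such were miR-200a (161.2 in aldosterone replicate 3), miR-429 and miR-196b (62.7 and 32.5 in vehicle replicate 3) and miR-24 (237 in vehicle replicate 5). For others, such as let-7d* (6.3 in vehicle replicate 1), it was not. The values of miR-21 and miR-709 are steps between a few top ranks of the quantile normalization, so their distances are not measured spreads.

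Probes for miRNAs of mouse herpesviruses, which were in no comparison, gave 7 signals above the authors' threshold on all 10 arrays, 5 of 29 for mouse cytomegalovirus and 2 of 10 for murine gammaherpesvirus. The cytomegalovirus probe miR-M23-1-5p was at 99.4 ± 34.7 with vehicle and 102.9 ± 17.6 with aldosterone, and the gammaherpesvirus probe miR-M1-9 at 44.1 ± 24.9 and 29.5 ± 5.2 (SD, n = 5), so a signal past the threshold on this array does not by itself show that the named miRNA is present. The spike control signal differed by 0.1901 on the log2 scale between aldosterone and vehicle.

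Aldosterone arrays were brighter before normalization, by a mean of 0.54 on the log2 scale in the median of commonly detected probes, in 5 of 5 pairs. Without normalization 96% of tested probes were higher, but a median is not moved by a few very bright probes, so this share does not test them. The dim vehicle replicate 2 does not account for it, since the difference averaged 0.51 and was positive in 4 of 4 pairs without replicate 2. After the spike control difference was taken off, 0.3523 remained, positive in 4 of 5 pairs (exact sign-flip p = 0.1875), so labelling or scanning shared with the spike controls and a larger miRNA content with aldosterone cannot be told apart with 5 pairs. The stage at which the spike controls were added is not given, so taking off their difference may leave labelling in the 0.3523. Quantile normalization gives all arrays the same distribution of values, so a rise shared by all miRNAs, as a hypothesis, may be invisible in the comparisons of single miRNAs.

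The miR-200 family was higher with aldosterone in the fit with the replicate block. Its call ended once the correlation among the 3 members was estimated, with the same median log2 change of 0.107. The estimate was 0.691, with an adjusted p = 0.3808 in limma's camera, against 0.04518 at the preset correlation. This was the outcome predicted for members that vary together, but the test cannot decide it. Lists with an estimated correlation near 0 or below lost their calls too, such as miR-232427 (-0.071) with the replicate block and 75th percentile scaling. Overall brightness stays open, as the members' paired log2 ratios, less each pair's median, averaged 0.405 but were positive in only 4 of 5 pairs. These ratios are of background-subtracted signals without the offset, so 0.405 and 0.107 are on different scales. They ran from -0.05 in replicate 1 to 1.06 in replicate 2, which holds the dim vehicle array. Of the 16 splits that part all 5 pairs, 4 gave a list p as small (real 0.00301, smallest other 0.000454 with the labels of replicate 3 exchanged), and 16 splits are too few for a share under 0.05. A response of the family to aldosterone remains untested beyond this.

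Arrays with the same replicate number resembled each other in both groups, most visibly for miR-210. Chance pairing is excluded: of 100 re-pairings of the arrays 1, the labelled one, gave as many probes that differ between numbers (real 10, highest other 6). Array brightness stays open, since 40% of these probes, 4 of 10, followed the number of detected probes, too few probes to place the share above or below an even split. For miR-2137 the steps between numbers are those of a few top ranks. The shared title codes may stand for a culture or a round of work, and the labels do not say, so no biological explanation was tested.

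For the comparison of aldosterone with vehicle, chance is not excluded. Of 100 splits of the arrays into 5 and 5, 79 gave at least as many probes at an unadjusted p under 0.05 (real 8, highest other 76). The real grouping parts all pairs, whereas splits that keep a pair together turn differences between replicate numbers into group differences. This share is therefore not a fair reference for paired arrays. The count past the adjusted threshold decides nothing here, since a real count of 0 is reached by any split (100 of 100, highest other 1). The split with 76 put both arrays of replicates 1 and 3 on one side and both of replicates 2 and 4 on the other, which points to a structure of the samples. Its sides also differed in detected probes (means 465.4 and 387), so replicate number and array brightness both stay open as its source. With the replicate block, 3 of the 16 splits that part all pairs gave as many (real 19, highest other 37, with replicates 2, 4 and 5 exchanged), and these are too few for a share under 0.05.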

How the results depend on the processing

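The alternatives chosen after seeing the data were normexp with an offset of 1 or on the blank spots, spike control scaling, leaving out pairs for the detected probes, and those that join the replicate block with another choice. The count of miRNA probes past the adjusted threshold was 0 under 42 of 43 alternatives, the other being an unadjusted p under 0.05, with 8. The replicate block changed no call on single probes, on detected probes or on the title styles. For the miRNA lists, 0 passed under 30 of 40 alternatives. The replicate block gave 1 (miR-200), 75th percentile scaling 4, no filter on dim probes 1 (endothelium and fibroblast markers) and spike control scaling 1 (embryonic stem cell clusters, lower). Leaving out single arrays or pairs gave 0 to 1 without the block (1 being the miR-466, miR-467 and miR-669 cluster without aldosterone replicate 3 or vehicle replicate 2), and with it 1 without replicate 1 (miR-200) and 3 without replicate 3 (miR-200, miR-30 and miR-29). The replicate block gave 4 with 75th percentile scaling and 3 with spike control scaling. Of these 20 list calls 0 passed with an estimated correlation (smallest adjusted p = 0.1369). Calls ended also where that correlation was near 0 (0.0147 for endothelium and fibroblast markers without the filter), so their loss does not name a cause. Otherwise the cause was not tested. The miR-17~92 median log2 change reversed to -0.022 under 75th percentile scaling, with and without the block, where the median of all probes lay at -0.044, so the test counted the list as higher. Of the 75 named miRNAs, 25 changed sign under that scaling, 26 without normalization and 18 under spike control scaling (each with or without the block), 28 in the deposited table and 0 to 4 under each other alternative. The share of tested probes that were higher was 53% as reported, 13.5% under 75th percentile scaling, 75.6% under spike control scaling, 96% without normalization and 85.6% in the deposited table, whose median log2 change was 0.311 and in which 24 probes were higher and 0 lower at an unadjusted p under 0.05. Without normalization and with the block, 160 were higher and 0 lower at that level, with 0 past the adjusted threshold. Under every alternative run, among others, miR-21 (0.345 to 1.04), miR-29b (0.202 to 1.211), miR-30a and miR-200a stayed on the higher side and miR-3102-3p.2, miR-877, miR-93* and miR-290-5p on the lower, none past the threshold. The difference in detected probes was 29.4 to 100 and never past it. Slide or scan batch as a block was not run. Signal over background is a limit for dim probes: blank spots had an SD of 0.939 to 1.34, against under 10 units for most of the miRNAs named by smallest p.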

Other observations

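The probes that moved one way in all 5 same-numbered pairs, chosen after their values were seen, include miRNAs outside the groups above. On the higher side miR-15a, a relative of miR-16 that restrains the cell cycle, was at 65.1 ± 13.1 with aldosterone and 49.5 ± 18.5 with vehicle (log2 change 0.22, SE 0.13; SD, n = 5), miR-130b at 14.4 ± 2.74 and 11.2 ± 3.08, and miR-374 at 6.86 ± 1.76 and 5.21 ± 1.80. On the lower side miR-92b* had a log2 change of -0.29 (SE 0.17) and stood at 281.8 ± 59.8 in vehicle. None passed the threshold (limma adjusted p = 0.9445). They are among 26 probes that moved one way in all pairs, against 26.9 expected by chance if no probe were tied. With 58 tested probes tied in a pair, the chance number is somewhat lower than that.

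The first principal component of the normalized log2 values held 52.2% of the variance. At its ends lay the arrays with the most and the fewest detected probes: both arrays of replicate 3 (scores -2.9 and -2.75, with 583 and 495 detected probes) on one side, and vehicle replicates 2 and 4 (4.55 and 2.14, with 275 and 347) on the other. Within pairs the array with fewer detected probes lay nearer the side of vehicle replicate 2 in 3 of 5, and 5 pairs are too few for a correlation, so whether the component goes with brightness or with replicate number is left open.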
